A study of Mus musculus with 6 samples.

How the data were processed

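RNA-seq of 6 libraries of primary mouse chondrocytes was used, 3 Nf2-knockout and 3 control. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, poly(A) RNA was captured with oligo(dT) beads, and whether the library kit keeps the strand is not given in the sources used here. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and edgeR, without their roles or order, and the genome build is not given in the sources used here.

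The authors deposited 1 table with a read count and an FPKM value for each of 55401 genes and each library, together with gene ontology and pathway terms and gene positions. The deposited counts are whole numbers whose totals differ between libraries, from 50906043 to 63748798, and 27103 genes had a count in at least 1 library. How the authors obtained them is not stated, and StringTie is named among the tools, so they may be rounded estimates of coverage and not reads assigned one by one. The deposited FPKM values (fragments scaled to transcript length and library size) were normalised by the authors for depth and length, and each count of 0 was written as an FPKM of 0.0001. Positions were equal to those of GENCODE M21, an annotation of the GRCm38 build, for 94.2% of the 55141 genes with an entry there, so positions are given as GRCm38. Where several genes shared a symbol, the one with the lowest Ensembl identifier kept it. No gene was left out of the library totals.

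The design fixed before the data were examined assumed a table of FPKM and named edgeR's quasi-likelihood test for the case that it held raw counts. Because counts are present, that test was the main one (R 4.3.3, edgeR 4.0.16: filterByExpr, TMM factors, glmQLFit and glmQLFTest on group alone), two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. It tested 18218 genes. Fold changes carry edgeR's prior count of 0.125. Their SE was derived from the test, as the absolute log2 fold change over the square root of its F statistic. It is therefore approximate as a measure of distance from a value other than no change. Each library held at least 50906043 counts, and a count of 0 over a group was bounded at a floor of 3 counts over the group, which covers counting error only. Single values were compared by the exact two-sided permutation test, whose smallest p with 3 against 3 libraries is 0.1.

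Before the data were examined, 20 process lists and 13 lists of cell type markers were fixed, covering cartilage, hypertrophy, YAP and TEAD targets, Hippo, PTH1R, cAMP, cell cycle, matrix degradation, fibroblastic matrix, Hedgehog, Wnt, TGF-β and BMP, FGF, unfolded protein response, hypoxia, interferon, cholesterol, oxidative phosphorylation, p53 and cytoskeletal genes, and markers of osteoblasts, osteoclasts, macrophages, neutrophils, lymphocytes, erythroid, endothelial, pericyte, skeletal muscle, adipocyte, Schwann, tendon and epithelial cells. In all, 33 genes stood in more than 1 list. Lists with at least 5 tested genes (29 lists) were tested together by camera in limma 3.58.1 with a preset correlation of 0.01, which asks whether a list's genes rank higher or lower than the other genes. Terms of 15 to 300 tested genes were tested likewise. As alternatives, camera used a correlation estimated from the data, and fry asked whether the genes of a list move, on balance, in 1 direction, without comparing them with other genes.

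The rule for named genes was also fixed before the data were examined. It took 19 genes tied to the question whatever their values, the 10 largest rises and 10 largest falls among changed genes with a full name and no overlap between groups, up to 4 members of each list with the smallest p-values, the 3 most abundant markers of each cell type and 4 members of each named term. Some genes that the rule takes are not reported here. The genes Tagln2, Gadd45b, Timp3 and Abcc9, the 20 genes with the largest changes at a mean FPKM of at least 1 and the genes of the chromosome regions were chosen after their values were seen.

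Tests were checked on simulated counts drawn from the means, dispersions and library sizes of these data, with known changes. Of genes changed 1.5-fold, 2-fold and 4-fold, the test recovered 1.52% of 66, 29.2% of 65 and 51.6% of 62, at median log2 errors of −0.05, 0.03 and 0.03. Among 17520 tested genes it made 56 calls, 4 of them false (7.14%) and 0 with the wrong sign. The real data gave 1693 calls. Because the adjustment depends on how many genes change, the shares recovered in the draws do not carry over to the real comparison. A raised list was found and 0 of 20 unchanged lists were called. The draws did not make genes vary together, so they cannot show how often camera falsely calls lists whose genes do. Of the 10 equal splits of the real libraries, 4 called at least 10 lists. The true grouping called 10 and the highest other split 12.

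Alternatives planned before the data were examined were DESeq2 1.42.0, its size factors, no filter on low counts, the replicate number as a block, leaving out each library in turn, and limma on the FPKM values with pseudocounts of 1 and 0.1, filters of mean FPKM of at least 1 and at least 5 or none, rescaling to a common sum, median-of-ratios scaling, no intensity trend and robust estimation. The base fit of limma-trend on log2(FPKM + 1) was the test that the design had fixed for a table of FPKM. Its use beside the count test and the block combined with fry were added after seeing the data. No 2 libraries of a group were alike within sampling noise, with a chi-square per degree of freedom of 59.3 to 99.4 over the pairs. No library batch or date is given in the labels. As a check of the labels, Xist was counted in each library, from 14622 to 27376 counts, and 4 Y-linked genes together had 0 counts in 5 libraries and 4 in control replicate 3.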

Results

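To explore what the loss of Nf2 does to the transcriptome of cartilage cells, poly(A) RNA was sequenced from primary mouse chondrocytes, which are cartilage cells put into culture, here under conditions that the series describes as including differentiation. The libraries fell into 2 groups of 3, Nf2-knockout and control, the latter carrying the floxed Nf2 gene without its deletion. Nf2 encodes merlin, a membrane-associated protein of the ezrin, radixin and moesin (ERM) family that acts upstream of the Hippo kinases. The title of the series names the parathyroid hormone receptor PTH1R, β-arrestin 2 and skeletal integrity, so the genes of that receptor's signalling and of the skeleton were among those examined. The total count per library was 50906043, 61392041 and 63748798 in Nf2-knockout replicates 1 to 3, and 61103617, 55516143 and 59635218 in control replicates 1 to 3. Between 21289 and 22108 genes had at least 1 count in a library. Nothing in the labels says that replicates came from separate animals or cultures, so each p-value measures only the spread between these libraries, which may be technical. Expression is given in CPM (counts scaled to a common library size) as mean ± SD with n = 3 in each group, fold changes are log2 of Nf2-knockout over control, and adjusted p-values of genes are from edgeR.

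Nf2 itself was lower in each Nf2-knockout library than in each control library, but its transcripts remained. Nf2 (ENSMUSG00000009073, chromosome 11, 4765845 to 4849536, minus strand, GRCm38) stood at 95.3 ± 6.59 CPM in Nf2-knockout and 126.9 ± 5.32 CPM in control libraries, 24.9% below control. Its log2 fold change was −0.41 (SE 0.0866, adjusted p = 0.0305), and the exact two-sided permutation test of 3 against 3 libraries gave p = 0.1, the smallest value it allows. The 3 knockout libraries held 4592, 6351 and 6503 counts of Nf2, and the controls 7448, 7153 and 6979. Counts were made over the whole gene, and which exons the deletion removes is not given in the sources used here, so transcripts with and without those exons could not be separated. The call for Nf2 was lost without any 1 of the 6 libraries, with log2 fold changes from −0.45 to −0.34 and adjusted p from 0.0518 to 0.123. The treatment label of the Nf2-knockout libraries names overexpression of TCF21, a transcription factor that their titles do not mention. Tcf21 (chromosome 10, 22817281 to 22820174) had 0, 2 and 0 counts in Nf2-knockout and 0, 0 and 0 in control libraries, too few to test.

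The 2 groups separated on the first principal component, which held 38.3% of the variance, with the 3 Nf2-knockout libraries on one side and the 3 controls on the other. The second component, with 18.9%, separated libraries within both groups. Of 18218 genes tested, 1693 (9.29%) changed, of which 749 rose and 944 fell in Nf2-knockout libraries. A change of at least 2-fold was found for 747 genes, with 324 higher and 423 lower. At an unadjusted p under 0.05 edgeR had 4518 of the 18218 genes, the background for such counts in single lists. The values of the groups did not overlap for 5991 tested genes (32.9%), where chance gives 10%. Rises made up 44.2% of the changed genes. The balance of rises and falls depended on the scaling: limma-trend on the deposited FPKM called 1039 rises and 596 falls (63.5% rises), and with median-of-ratios scaling of the FPKM, over the same number of tested genes (12139), 655 and 769 (46%). After rescaling to a common sum it called 1349 and 513 of 14560 tested genes (72.5%). The median log2 fold change of all tested genes was 0.0802, 0.00605 and 0.131 in these fits, against −0.01 for the counts. Single libraries also moved the number of changed genes, to 629 without Nf2-knockout replicate 1, 705 without control replicate 2, 744 without Nf2-knockout replicate 3 and 973 without control replicate 1, and the number changed at least 2-fold to 394, 424, 447 and 533. A gene named as changed kept its call in each of the 6 fits that left out 1 library unless a smaller number of those fits is given.

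**Figure D1:**
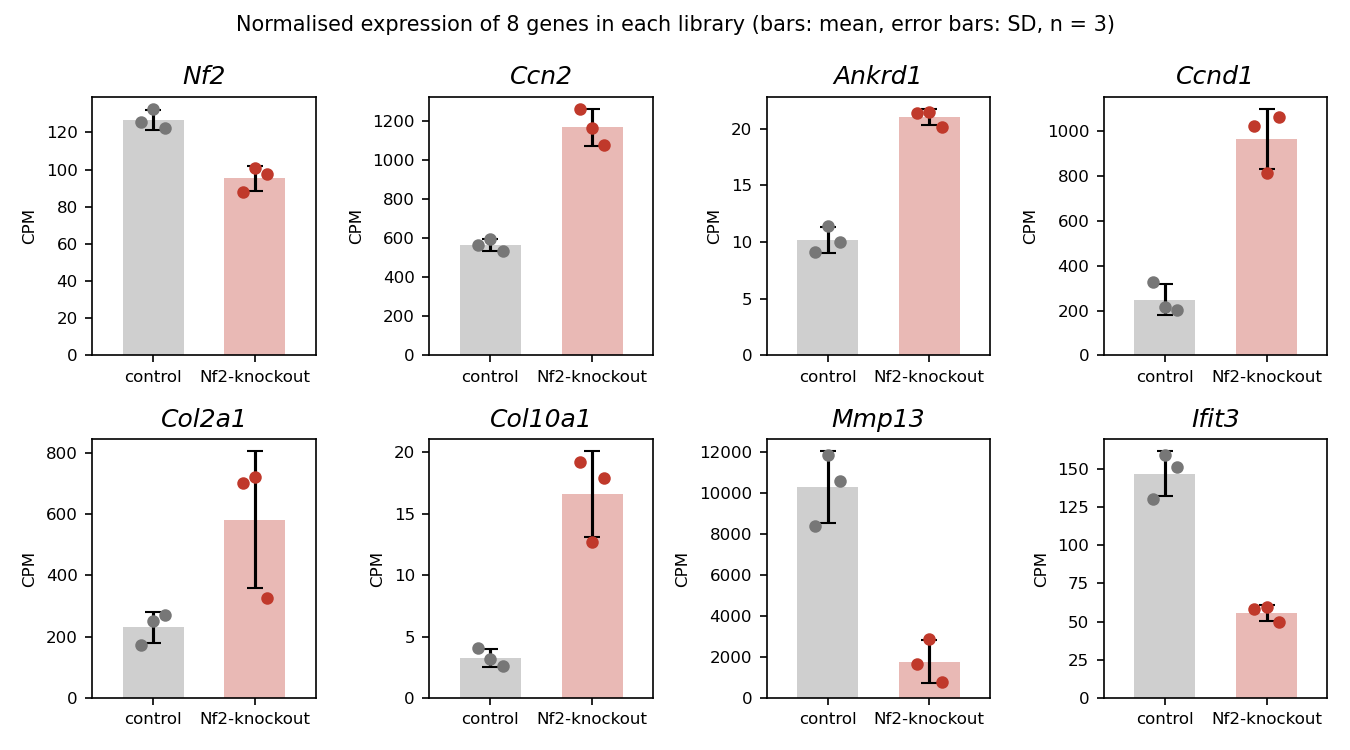
Normalised expression (CPM, vertical axes from 0) of 8 genes in the 3 control and 3 Nf2-knockout libraries. Points are libraries, bars are group means and error bars are SD with n = 3. Ccn2, Ankrd1, Ccnd1, Col2a1 and Col10a1 lie higher in each Nf2-knockout library than in each control, and Nf2, Mmp13 and Ifit3 lie lower.

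Genes of cell division were higher in Nf2-knockout libraries. Of 40 tested genes of the cell cycle list, 19 rose and 0 fell, and adjusted over the list alone 35 rose and 0 fell. Ccnd1, which encodes cyclin D1 and drives entry into the cell cycle, rose from 247 ± 69.1 to 964 ± 134 CPM (log2 fold change 1.96, SE 0.21, adjusted p = 0.00442, chromosome 7, 144929931 to 144939925). Rrm2, a subunit of ribonucleotide reductase, rose by 1.72 on the log2 scale, Ccne1 (cyclin E1) by 0.84 and the replicative helicase subunit Mcm2 by 0.90. Mki67, the gene of the proliferation marker Ki-67, rose from 16.9 ± 0.808 to 32.4 ± 7.08 CPM (log2 fold change 0.94, adjusted p = 0.0195), a call held in 1 of the 6 fits without 1 library. The median of the list was 0.76, and camera with a preset correlation gave an adjusted p = 5.75e-19. The list had an adjusted p = 0.328 with an estimated correlation, which ends the call. Between 5 members (without Nf2-knockout replicate 3 or without control replicate 2) and 12 members (without Nf2-knockout replicate 1) rose when 1 library was left out.

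Genes of the actin cytoskeleton and targets of YAP and TEAD, the transcriptional regulators downstream of the Hippo kinases, were higher as groups. Pericyte and smooth muscle markers were higher with them (median 0.53, camera adjusted p = 0.0246, not passing with an estimated correlation at adjusted p = 0.511), and Acta2 stands in both that list and the cytoskeletal one. More cells of that type in the Nf2-knockout cultures are therefore not excluded as a source. In the list of ERM proteins and actin cytoskeleton, 10 of 32 tested genes rose and 1 fell (12 and 1 adjusted over the list alone). The actin bundler gene Actn1 rose from 164 ± 5.87 to 266 ± 11.1 CPM (log2 fold change 0.69) and the ERM gene Msn, which encodes moesin, by 0.55 on the log2 scale (3 of 6 fits). The exception was Tagln2, an actin-binding calponin family gene, with a log2 fold change of −0.49 (1 of 6 fits). Among 29 tested YAP and TEAD targets, 5 rose and 2 fell (10 and 2 adjusted over the list alone). Ccn2, a secreted matricellular protein and widely used YAP target, rose from 564 ± 30.7 to 1167 ± 92.8 CPM (log2 fold change 1.05, SE 0.0954, adjusted p = 0.00332, chromosome 10, 24595442 to 24598683), and Ankrd1, a second common readout, from 10.2 ± 1.16 to 21.03 ± 0.735 CPM (1.04, SE 0.127, adjusted p = 0.00601, chromosome 19, 36111961 to 36119910). Both falls were stress-response genes, Gadd45a (−1.25) and Gadd45b (−0.61, 0 of 6 fits). Ccn1, another common target, stood at 719 ± 20.6 against 584 ± 51.2 CPM and did not pass the test (0.30, adjusted p = 0.0945). Median log2 fold changes were 0.23 for the cytoskeletal list (adjusted p = 3.49e-05) and 0.32 for the target list (adjusted p = 0.0078). Both had an adjusted p = 0.328 with an estimated correlation. With 1 library left out, 4 to 7 cytoskeletal genes and 2 to 5 YAP and TEAD targets rose, with the fewest targets without Nf2-knockout replicate 1.

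Of the Hippo pathway components themselves, 3 rose and 3 fell among 29 tested genes (4 and 5 adjusted over the list alone). The list median was −0.05 and its mean 0.02, of opposite sign, with camera's direction down (adjusted p = 0.894). The numbers were 1 and 1 without Nf2-knockout replicate 1 or control replicate 1, 1 and 2 without Nf2-knockout replicate 2 and 2 and 1 without each other library. The medians ran from −0.10 (without Nf2-knockout replicate 2) to −0.02 (without Nf2-knockout replicate 1 or 3). The transcription factor Tead4 rose from 2.51 ± 0.569 to 9.27 ± 2.34 CPM (log2 fold change 1.89), and the protocadherin Dchs1 fell from 10.9 ± 1.9 to 3.88 ± 0.52 CPM (−1.49). Amot, which encodes the YAP-binding scaffold angiomotin, fell by 0.45 on the log2 scale (1 of 6 fits). Yap1 stood at 125 ± 5.45 against 116 ± 3.68 CPM (0.10, adjusted p = 0.491), and Wwtr1, which encodes TAZ, at 98.9 ± 3.85 against 99.5 ± 10.3 CPM (−0.01, adjusted p = 0.975). The sign of the Wwtr1 value differed between scalings.

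Of 36 tested PTH1R signalling components, 2 rose and 0 fell (2 and 0 adjusted over the list alone). At an unadjusted p under 0.05 edgeR had 16 of the 36, against 4518 of all 18218 tested genes. The list did not pass (median −0.11, camera adjusted p = 0.634). Without control replicate 1 there were 1 rise and 1 fall, without Nf2-knockout replicate 1 or 2 or control replicate 3 only 1 rise, and without Nf2-knockout replicate 3 or control replicate 2 edgeR called 0, with 11 at an unadjusted p under 0.05 in either fit. The receptor gene Pth1r (chromosome 9, 110722085 to 110747145) stood at 5.95 ± 1.5 CPM in Nf2-knockout and 14.5 ± 5.6 CPM in control libraries, with a log2 fold change of −1.28 (SE 0.332) that did not pass (adjusted p = 0.0582). Its adjusted p was 0.0329 without control replicate 1 and 0.00248 with DESeq2. Arrb2, the gene of β-arrestin 2 (chromosome 11, 70432635 to 70440828), stood at 3.53 ± 0.677 against 4.56 ± 0.464 CPM (−0.37, adjusted p = 0.364). Arrb1, the gene of β-arrestin 1, varied widely, at 15.8 ± 17.3 against 3.53 ± 2.71 CPM (2.16, SE 0.888, adjusted p = 0.189), and its log2 fold change lay between 0.73 and 3.01 with 1 library left out. The 2 rises were Grk5, a G protein-coupled receptor kinase (0.90, 4 of 6 fits), and the phospholipase gene Plcb3 (0.41, 0 of 6 fits). Pthlh, the gene of a ligand of the receptor, had 8, 0 and 0 counts in Nf2-knockout and 0, 0 and 0 in control libraries and was not tested. Among 27 immediate response genes of cAMP and CREB, 3 rose and 2 fell (7 and 4 adjusted over the list alone). The nuclear receptor gene Nr4a3 fell from 11.5 ± 2.2 to 3.9 ± 0.839 CPM (−1.56), whereas the cyclooxygenase gene Ptgs2 rose by 1.76 (4 of 6 fits). That list did not pass (median 0.04, mean −0.02, camera direction up, adjusted p = 0.854). Rises and falls numbered 1 and 1 without Nf2-knockout replicate 1 or 3, 2 and 1 without control replicate 1 or 3, and 0 and 1 without control replicate 2, where the median was −0.09, camera's direction was down and edgeR had 10 genes at an unadjusted p under 0.05.

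Cartilage and hypertrophy genes moved in both directions. Genes of cartilage matrix and chondrocyte identity summed to 2024 CPM in Nf2-knockout and 1566 CPM in control libraries. Those of the fibroblastic matrix list summed to 31660 and 33610 CPM. How far the cultured cells were differentiated chondrocytes was not tested. Col10a1, the collagen of hypertrophic chondrocytes, rose from 3.25 ± 0.733 to 16.6 ± 3.48 CPM (log2 fold change 2.35, SE 0.241, adjusted p = 0.00417, chromosome 10, 34389981 to 34397085). Col2a1, the main cartilage collagen, rose from 231 ± 50.7 to 581 ± 223 CPM (1.33, SE 0.316, adjusted p = 0.0446, chromosome 15, 97975602 to 98004695). The call for Col2a1 was held without Nf2-knockout replicate 3 and lost without each other library, with adjusted p from 0.0841 to 0.129. In edgeR it was also lost with no filter on low counts (adjusted p = 0.0513) and with the replicate block (0.114). In limma on FPKM it was lost without a filter (0.0992), with median-of-ratios scaling (0.0654) and with robust estimation (0.0525). DESeq2, its size factors and the other FPKM fits kept it. The cartilage regulator Sox9 (18.4 ± 3.91 against 23.7 ± 3.81 CPM, adjusted p = 0.298) and the proteoglycan gene Acan (8.18 ± 4.51 against 12.6 ± 2.49 CPM, adjusted p = 0.413) did not pass. Of 27 tested genes of cartilage matrix and chondrocyte identity, 2 rose and 2 fell, with equal numbers adjusted over the list alone (2 and 2). Cytl1, a secreted chondrocyte protein, rose by 2.68 (5 of 6 fits), and the fibril-associated collagen gene Col9a2 fell from 70.0 ± 17.2 to 23.8 ± 11.7 CPM (−1.55, 1 of 6 fits). Of 25 hypertrophy and mineralization genes, 2 rose and 2 fell (4 and 4 adjusted over the list alone). Slc20a2, a phosphate transporter, rose by 0.53, and Vegfa, an angiogenic growth factor, had a log2 fold change of −0.53 (1 of 6 fits). Runx2, a regulator of hypertrophy, stood at 13.3 ± 0.565 against 20.1 ± 7.28 CPM (adjusted p = 0.229), and Ihh had 5, 10 and 0 counts in Nf2-knockout and 0, 8 and 0 in control libraries, too few to test. Neither list passed: cartilage had a median of 0.02, a mean of −0.08 and camera direction down (adjusted p = 0.894), and hypertrophy a median of −0.02 with camera direction up (adjusted p = 0.953). The cartilage median depended on single libraries, at −0.35 without Nf2-knockout replicate 2, −0.26 without control replicate 1, −0.23 without Nf2-knockout replicate 1, −0.06 without control replicate 2, 0.05 without control replicate 3 and 0.18 with camera direction up without Nf2-knockout replicate 3. The list then had 1 rise and 1 fall without Nf2-knockout replicate 2 or control replicate 3, 1 rise without Nf2-knockout replicate 1 or control replicate 1, 3 rises without Nf2-knockout replicate 3 and none by edgeR without control replicate 2 (10 at an unadjusted p under 0.05). The hypertrophy median lay between −0.13 without Nf2-knockout replicate 1 (no fall) and 0.02 without control replicate 1, and 1 gene fell without any 1 control.

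Genes of matrix degradation and inflammation were lower as a group, with exceptions. Macrophage and myeloid markers fell with them (median −2.22, 6 of 15 fell), and Mmp12 is an enzyme of macrophages. For these markers camera gave an adjusted p = 5.36e-08, and an adjusted p = 0.486 with an estimated correlation. The fall therefore cannot be assigned to chondrocytes alone. The list summed to 22660 CPM in control and 11800 CPM in Nf2-knockout libraries, and the markers to 274 and 84.8 CPM. Mmp13 alone held 10273 CPM of the control sum and 1773 CPM of the Nf2-knockout sum, so it carried most of the summed fall. How much of each gene's RNA came from macrophages was not measured. Mmp13, the collagenase of hypertrophic cartilage and a member also of the hypertrophy list, fell from 10273 ± 1748 to 1773 ± 1054 CPM (log2 fold change −2.53, SE 0.438, adjusted p = 0.0169, chromosome 9, 7272514 to 7283331). Its call was lost without Nf2-knockout replicate 1 (adjusted p = 0.0742) and without control replicate 2 (adjusted p = 0.0571). The metalloelastase gene Mmp12 fell from 10.7 ± 1.29 to 0.476 ± 0.26 CPM (−4.47), the stromelysin gene Mmp10 from 42.3 ± 10.1 to 9.40 ± 1.64 CPM (−2.17) and the aggrecanase gene Adamts4 from 40.7 ± 6.43 to 11.5 ± 2.67 CPM (−1.82). Mmp13, Mmp12 and Mmp10 lie in 1 region of chromosome 9 in which 8 of 11 tested genes fell. The other aggrecanase gene, Adamts5, rose from 250 ± 7.13 to 419 ± 25.5 CPM (0.74), as did Ptgs2 and the metalloproteinase inhibitor Timp3 (0.86, 4 of 6 fits). In all, 3 of 26 tested genes of matrix degradation and inflammation rose and 10 fell (3 and 16 adjusted over the list alone), with a median of −1.02 (camera adjusted p = 1.06e-09). The list had an adjusted p = 0.328 with an estimated correlation, and 7 to 12 members fell and 1 (without control replicate 2) to 3 rose with 1 library left out. In the fibroblastic matrix list, 2 of 26 tested genes rose and 4 fell (2 and 8 adjusted over the list alone), and the list did not pass (median −0.03, adjusted p = 0.318), except without Nf2-knockout replicate 3 (median −0.12, 5 falls, adjusted p = 0.0104). Only 1 rose and 1 fell without Nf2-knockout replicate 1 or any 1 control, and the median was 0.03 without Nf2-knockout replicate 1, 0.02 without control replicate 3 and −0.10 without control replicate 1. The matricellular gene Thbs1 rose from 884 ± 37.5 to 2481 ± 80.3 CPM (1.49), and the growth factor receptor gene Pdgfra fell from 615 ± 21.5 to 229 ± 39.7 CPM (−1.42), with the proteoglycan gene Lum at −1.78 (2 of 6 fits).

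Interferon response genes were lower, and markers of macrophages were lower with them. Of 29 tested interferon response genes, 0 rose and 16 fell (0 and 26 adjusted over the list alone), with a median of −1.16. Ifit3, an interferon-induced gene, fell from 147 ± 14.8 to 55.9 ± 5.21 CPM (log2 fold change −1.39, SE 0.114, adjusted p = 0.00317, chromosome 19, 34583531 to 34588731), Oasl2 from 11.9 ± 0.955 to 3.16 ± 0.36 CPM (−1.91) and the interferon regulator Irf7 by 1.20 on the log2 scale. Of 15 tested macrophage and myeloid markers, 0 rose and 6 fell (0 and 11 adjusted over the list alone), with a median of −2.22. The complement genes C1qa (−2.96, 0 of 6 fits) and C1qb (−2.85, 1 of 6 fits) and the lysosomal marker Cd68 (27.9 ± 5.57 against 47.3 ± 5.85 CPM, 0 of 6 fits) were among the falls, and Lyz2 stood at 29.9 ± 16.5 against 116 ± 78.3 CPM without passing (adjusted p = 0.089). The markers summed to 115.5, 88.8 and 50.2 CPM in the Nf2-knockout and 164.4, 440.5 and 217.1 CPM in the control libraries, highest in control replicate 2. Camera gave an adjusted p = 1.1e-19 for interferon genes and 5.36e-08 for macrophage markers, and the lists had an adjusted p = 0.328 and an adjusted p = 0.486 with an estimated correlation. Without control replicate 2 the macrophage median was −1.58 and 0 markers passed, with 10 of 15 at an unadjusted p under 0.05. No marker passed without Nf2-knockout replicate 1 or 3 or control replicate 3 either, and between 6 (without Nf2-knockout replicate 1) and 14 interferon genes (without control replicate 3) fell with 1 library left out.

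Of 10 pericyte and smooth muscle markers, 3 rose and 1 fell (4 and 1 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 0.0246, and adjusted p = 0.511 with an estimated correlation). The proteoglycan gene Cspg4 rose from 35.7 ± 3.87 to 75.7 ± 9.01 CPM and Rgs5 from 11.3 ± 5.59 to 44.0 ± 3.93 CPM, while Acta2, smooth muscle actin and also a member of the cytoskeletal list, rose from 139 ± 12.1 to 355 ± 151 CPM (3 of 6 fits). The channel subunit gene Abcc9 fell (−2.67, 2 of 6 fits). That list was lost without control replicate 2 (median 0.15, adjusted p = 0.119) and without control replicate 3 (0.32, adjusted p = 0.172), and its median was 1.09 without control replicate 1. Of 7 osteoclast markers, 1 fell (0 rose, and 0 and 2 adjusted over the list alone), the proton pump subunit gene Atp6v0d2 (−1.65), with Ctsk at 1201 ± 244 against 1066 ± 192 CPM. Endothelial markers had 1 rise in 10 (1 and 0 adjusted over the list alone), the receptor gene Kdr (4.49 ± 0.766 against 1.75 ± 0.286 CPM, 2 of 6 fits), and Schwann and neural markers 1 fall in 7 (0 and 1), the cadherin gene Cdh19 (−1.44, 1 of 6 fits). None changed, also adjusted over the list alone, among 10 osteoblast markers (Col1a2 at 2297 ± 195 against 3125 ± 439 CPM, adjusted p = 0.0821), 10 skeletal muscle markers (Mylpf at 0.785 ± 0.22 against 1.14 ± 0.347 CPM), 11 adipocyte markers (Fabp4 at 337 ± 45.2 against 448 ± 94.6 CPM) and 8 tendon and perichondrium markers (Scx at 22.0 ± 1.81 against 18.5 ± 3.54 CPM). At an unadjusted p under 0.05 edgeR had 4, 0, 2 and 2 of these markers, in that order, and DESeq2 called 3, 0, 1 and 1. The medians were −0.45 for osteoclast (adjusted p = 0.157), 0.01 for endothelial (0.634), −0.31 for Schwann and neural (0.318), 0.09 for osteoblast (0.953, camera direction down), 0.17 for skeletal muscle (0.901, mean −0.05), −0.03 for adipocyte (0.894, camera direction up) and 0.24 for tendon markers (0.679). Osteoclast markers passed without Nf2-knockout replicate 3 (2 falls, adjusted p = 0.0104). With 1 library left out the medians ran from −0.60 (without Nf2-knockout replicate 1) to −0.12 (without Nf2-knockout replicate 2) for osteoclast, −0.32 (without Nf2-knockout replicate 3) to 0.21 (without control replicate 3) for endothelial and −0.69 (without Nf2-knockout replicate 2) to −0.07 (without Nf2-knockout replicate 3) for Schwann and neural markers. They ran from −0.03 (without Nf2-knockout replicate 1) to 0.22 (without Nf2-knockout replicate 3) for osteoblast and −0.24 (without control replicate 2) to 0.53 (without control replicate 3) for skeletal muscle markers. The ranges were −0.27 (without control replicate 2) to 0.17 (without control replicate 1, with 1 rise) for adipocyte and −0.08 (without Nf2-knockout replicate 3) to 0.33 (without control replicate 3) for tendon markers. Of the latter, 1 fell without Nf2-knockout replicate 2. Only 2 neutrophil, 1 lymphocyte, 2 erythroid and 3 epithelial markers had enough counts to test and 0 of them changed, also adjusted over the list alone, at an unadjusted p under 0.05 or with DESeq2, with S100a8 at 0.366 ± 0.35 against 0.598 ± 0.106 CPM, Ighm at 2.40 ± 1.89 against 1.09 ± 0.317 CPM, Hbb-bs at 0.0848 ± 0.147 against 0.274 ± 0.246 CPM and Krt10 at 4.69 ± 0.855 against 6.35 ± 1.35 CPM.

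Nuclear genes of oxidative phosphorylation were lower as a group and by modest amounts. Of 31 tested genes, 0 rose and 17 fell (0 and 23 adjusted over the list alone), with a median of −0.41. Atp5a1, a subunit of the ATP synthase, fell from 1245 ± 82.8 to 794 ± 52.4 CPM (log2 fold change −0.65, SE 0.0943, adjusted p = 0.0101, 5 of 6 fits), the complex III subunits Uqcrfs1 and Uqcrq by 0.55 and 0.49 (3 of 6 fits each) and the cytochrome oxidase subunit Cox8a by 0.65 (4 of 6 fits). Counts on the mitochondrial chromosome made up 7.58 ± 0.121% of each Nf2-knockout library and 9.01 ± 1.08% of each control library (exact permutation p = 0.1, the smallest that 3 against 3 allows). Camera gave an adjusted p = 5.32e-12, and the list had an adjusted p = 0.328 with an estimated correlation. The median lay between −0.48 and −0.38 with 1 library left out, and the number that fell was 1 without Nf2-knockout replicate 1, 2 without Nf2-knockout replicate 3, 3 without control replicate 2 and 9 to 11 without the others.

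**Figure D2:**
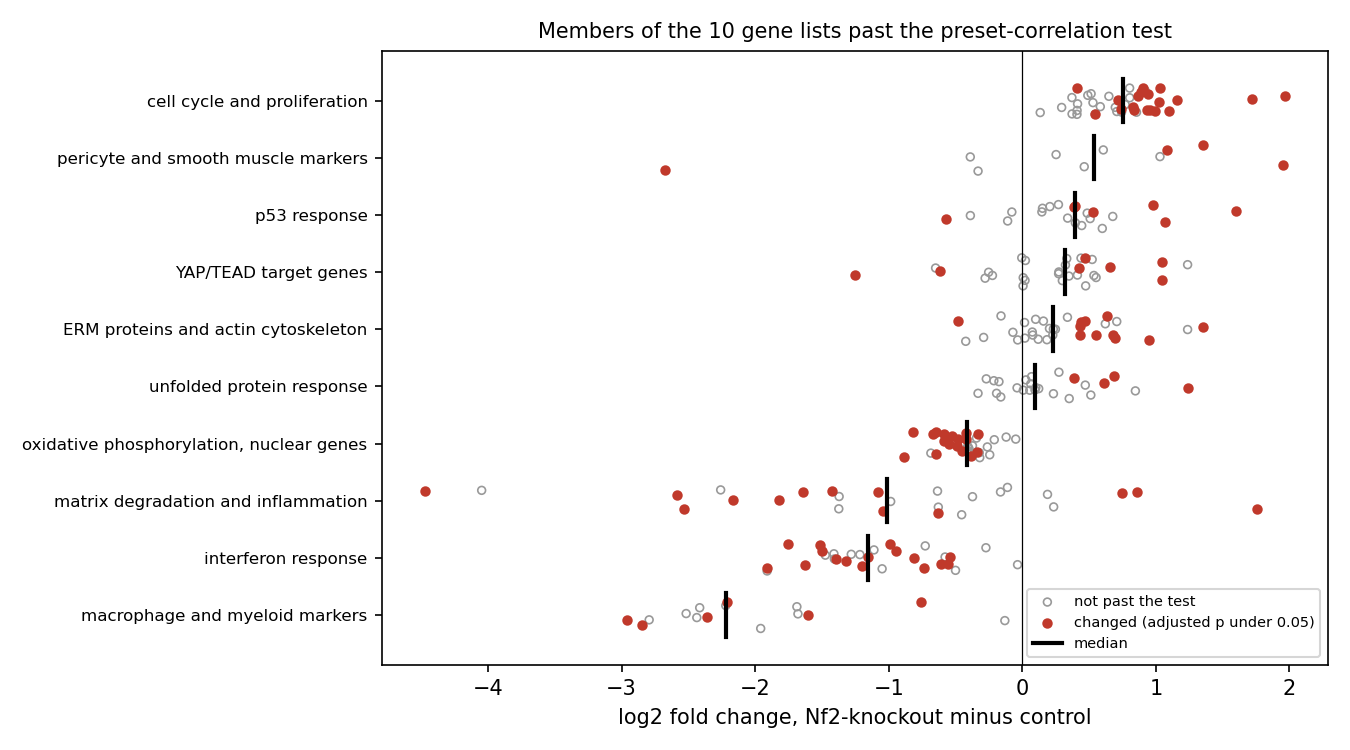
Log2 fold change (Nf2-knockout over control, horizontal axis) of the tested members of the 10 gene lists that passed camera with a preset correlation. Each point is a gene, filled where it changed, and the black bar is the list median, from −2.22 for macrophage and myeloid markers to 0.76 for cell cycle genes; points are scattered vertically only to be visible.

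Stress-response lists were slightly higher. Of 21 tested p53 response genes, 6 rose and 1 fell (11 and 2 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 6.32e-05, and adjusted p = 0.511 with an estimated correlation). The death receptor gene Fas rose from 22.8 ± 3.96 to 47.9 ± 6.29 CPM (1.07) and the stress cytokine gene Gdf15 from 22.8 ± 2.22 to 45.0 ± 8.51 CPM (0.98). Of 25 tested genes of the unfolded protein response, 4 rose and 0 fell, with equal numbers adjusted over the list alone (4 and 0), and the median was 0.09 (adjusted p = 0.048, and adjusted p = 0.511 with an estimated correlation). Chac1, a glutathione-degrading enzyme induced by stress, rose by 1.24 and the asparagine synthetase gene Asns by 0.68 (4 of 6 fits). The unfolded protein response list did not pass without Nf2-knockout replicate 1 (adjusted p = 0.0712), Nf2-knockout replicate 2 (0.0982) or control replicate 1 (0.144). Its rises numbered 1 without Nf2-knockout replicate 1, 3 without control replicate 3 (with 1 fall) and 2 without each other library. Its median ran from 0.05 without Nf2-knockout replicate 2 and 0.06 without control replicate 1 to 0.17 without Nf2-knockout replicate 3 and 0.18 without control replicate 3. Between 2 and 6 p53 response genes rose with 1 library left out, the fewest without Nf2-knockout replicate 1 or 3 or control replicate 2.

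The remaining signalling and metabolic lists did not pass. Of 27 TGF-β and BMP response genes, 7 rose and 3 fell (8 and 3 adjusted over the list alone, median 0.21, adjusted p = 0.155). The rises numbered 3 without control replicate 2 and 4 without Nf2-knockout replicate 1 or 3, and the median was 0.41 without control replicate 3 and 0.13 without control replicate 1. The BMP family gene Gdf10 rose from 7.54 ± 1.5 to 18.9 ± 2.27 CPM (1.33) and Ltbp1, which binds latent TGF-β, by 0.76, whereas Tgfb1 fell from 122 ± 4.84 to 71.1 ± 7.94 CPM (−0.78) and Pmepa1, an inhibitor of the pathway, by 0.85. Of 21 Wnt targets, 1 rose and 2 fell (2 and 3 adjusted over the list alone, median −0.14, adjusted p = 0.634). The Wnt median was 0.03 without control replicate 1, −0.34 without control replicate 2, −0.30 without control replicate 3 and −0.22 without Nf2-knockout replicate 3. There were 2 rises without Nf2-knockout replicate 2 or control replicate 1 and 1 fall without Nf2-knockout replicate 1 or 2 or control replicate 1 or 3. With all libraries the rise was Ccnd1, and the secreted Wnt modulator Dkk3 fell from 1592 ± 117 to 648 ± 113 CPM (−1.30). Of 14 Hedgehog pathway genes, 0 rose and 2 fell, with equal numbers adjusted over the list alone (0 and 2, median −0.11, mean 0.10, camera direction down, adjusted p = 0.594). The falls were the co-receptor genes Boc (−1.15, 4 of 6 fits), which lies in a region of chromosome 16 where 10 of 15 tested genes fell, and Gas1 (−0.74, 2 of 6 fits). The Hedgehog median was −0.04 without Nf2-knockout replicate 1 and −0.05 without control replicate 1 or 2. Of 21 FGF and ERK response genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone, median 0.04, adjusted p = 0.858), the rise being the ERK phosphatase gene Dusp6 (0.65) and the fall the receptor gene Fgfr1 (−0.34, 0 of 6 fits), with a median from −0.08 without control replicate 2 to 0.17 without Nf2-knockout replicate 2 or control replicate 1. Of 31 hypoxia and glycolysis genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone, median −0.18, adjusted p = 0.157, and 0.04 without Nf2-knockout replicate 2). No hypoxia gene fell in edgeR without any other 1 library (4 to 8 at an unadjusted p under 0.05), 2 rose without control replicate 3, and the median was −0.08 without Nf2-knockout replicate 3 and −0.10 without control replicate 1. Collagen prolyl hydroxylase P4ha2 rose by 0.67. Of 24 genes of cholesterol synthesis, 0 changed, also adjusted over the list alone (median 0.06, adjusted p = 0.634), where edgeR gave 1 an unadjusted p under 0.05 and DESeq2 called 0. Its median was −0.03 without control replicate 1, 0.17 without control replicate 2 and 0.10 without Nf2-knockout replicate 1.

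To look beyond the fixed lists, 2568 gene ontology and pathway terms were tested, of which 34 passed as higher and 56 as lower. In camera with an estimated correlation 0 of the terms passed, at an adjusted p = 0.911, and 89 had an unadjusted p under 0.05. Among the most significant higher terms were laminin binding (9 of 23 genes rose, 1 fell, adjusted p = 8.36e-05), DNA replication initiation (8 of 21 rose, 0 fell, adjusted p = 0.000221) and intermediate filament (12 of 42 rose, 2 fell, adjusted p = 0.00187), with terms of DNA replication and cyclin-dependent kinase between the last 2. The laminin receptor subunit Itga6 rose from 10.8 ± 1.3 to 39.5 ± 9.7 CPM (1.88), Tinagl1 by 1.83, and Gpc1, a cell-surface proteoglycan, fell by 1.24. Among filament genes, the desmosomal linker Dsp rose from 2.98 ± 0.75 to 32.1 ± 3.9 CPM (3.43), the keratin genes Krt7 by 2.12 and Krt19 by 1.98 and nestin, Nes, by 1.86. None of these filament genes stood in the list of epithelial markers, and a change in the mix of cells was not tested as their source. The lowest adjusted p-values among lower terms belonged to oxidative phosphorylation (0 of 124 rose, 34 fell, adjusted p = 3.26e-13), the respirasome (0 of 61 rose, 19 fell, adjusted p = 1.7e-11) and disease pathways that share those genes, followed by the tricarboxylic acid cycle (0 of 27 rose, 12 fell, adjusted p = 5.7e-06). Ppargc1a, which encodes the coactivator of mitochondrial biogenesis PGC-1α, fell from 138 ± 21 to 45.5 ± 5.52 CPM (−1.60), and the tricarboxylic acid cycle enzyme gene Idh2 fell by 1.02.

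The largest fitted changes belonged to genes of low counts. Of the 1693 changed genes, 42 had no count in any library of one group. Among changed genes with a full name and no overlap between groups, such genes hold the 10 largest rises and 9 of the 10 largest falls, so that only a lower bound of their fold can be given, against 3 counts over a group. The receptor gene Qrfpr was at least 97.9-fold higher in Nf2-knockout libraries (1.76 ± 0.597 CPM), the germ cell helicase gene Ddx4 at least 82.6-fold (1.44 ± 0.6 CPM) and Cyp4a12b at least 66.1-fold (1.18 ± 0.213 CPM). The pheromone-carrier gene Mup1 was at least 80.9-fold lower (1.32 ± 0.638 CPM in controls). Cyp4a12b and Mup1 belong to families of near-identical copies, among which reads may have been divided. The bounds of the other 7 rises ran from 25.9-fold to 43.6-fold and those of the other 8 falls from 16.4-fold to 41.4-fold, including the leukocyte genes Wdfy4 and Clec12a (4 of 6 fits each) and Cd22 (0 of 6 fits). The remaining fall, Elobl, which lies in a region of chromosome 11 where 11 of 17 tested genes fell, went from 100.4 ± 59.3 to 1.16 ± 0.199 CPM (−6.43, SE 0.481, adjusted p = 0.00304).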

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

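The fit on FPKM without any other altered choice was the design's test for a table of FPKM. Its use beside the count test and the block combined with fry were chosen only after the data were seen. The other alternatives were planned. The number of changed genes, 1693 with the counts, was 2955 with DESeq2, which included all 1693, and 1062 with limma-trend on FPKM without a filter, and lay between 629 and 1186 with 1 library left out. It stayed within 1.5 times the reported number with no filter on low counts (1337), with DESeq2 size factors (1664) and in the other FPKM fits (1203 to 1862). The number changed at least 2-fold, 747 with the counts, was 302 with limma-trend on log2(FPKM + 1), 477 with a pseudocount of 0.1, 247 without a filter, 210 at a mean FPKM of at least 5, 488 after rescaling to a common sum, 312 with median-of-ratios scaling, 299 without a trend and 293 with robust estimation, and lay between 394 and 700 with 1 library left out. A pseudocount lowers the fold of low genes by construction, and fewer libraries or genes enter the fits without a library or with a filter; for the other differences the cause was not tested.

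The fall of Nf2 kept its direction throughout. Its log2 fold change of −0.41 no longer passed in the FPKM fits at −0.29 (pseudocount 1, no filter, mean FPKM of at least 5, no trend, robust), −0.31 (pseudocount 0.1) and −0.25 (rescaled to a common sum), with adjusted p from 0.0525 to 0.143, nor without any 1 library (−0.45 to −0.34). It passed with DESeq2, without a filter on low counts, with DESeq2 size factors and with median-of-ratios scaling of FPKM. The value of Wwtr1, which passed no test, turned from −0.01 to 0.0070 with DESeq2, 0.0071 with DESeq2 size factors, 0.0926 with limma-trend on log2(FPKM + 1), without a filter, at a mean FPKM of at least 5, without a trend and with robust estimation, 0.0972 with a pseudocount of 0.1, 0.148 after rescaling to a common sum and 0.0061 with median-of-ratios scaling, and to 0.026 and 0.0789 without Nf2-knockout replicate 2 and without control replicate 1, and was lowest at −0.0614 without control replicate 2. That of Elob, likewise not called, turned from −0.13 to 0.0291 with FPKM rescaled to a common sum. The cause was not tested.

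Replicate numbers are shared between the groups, but nothing says that they pair the libraries. The deviations of same-numbered libraries from their group means had correlations of −0.0895, 0.0296 and 0.0234, and neither Nf2-knockout replicate 1 nor 3 correlated best with its own number (0.106 with control replicate 2 and 0.122 with control replicate 1), so the numbers were not taken to pair them. With the replicate number as a block, 923 genes changed, 877 of them among the 1693, and 485 changed at least 2-fold. Nf2 stood at −0.41 (adjusted p = 0.0695), the unfolded protein response list at an adjusted p = 0.0697, and 102 terms passed.

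Of the 10 lists and 90 terms that passed camera with a preset correlation, 0 lists and 0 terms passed in camera with an estimated correlation, where 3 lists and 89 terms had an unadjusted p under 0.05. With fry 8 lists passed, among them TGF-β and BMP response (adjusted p = 0.0253) and osteoclast markers (adjusted p = 0.0197), and p53 response, unfolded protein response, macrophage and pericyte markers did not. With the block and fry together each of the 10 lists lost its call (adjusted p from 0.1 to 0.24). The list of YAP and TEAD targets had an adjusted p = 0.278 and that of the unfolded protein response 0.142 at a mean FPKM of at least 5, the latter also 0.0532 with median-of-ratios scaling. Pericyte markers lost the call in 5 FPKM fits (adjusted p from 0.0674 to 0.159), osteoclast markers passed without a filter on counts (0.0233) and in 2 FPKM fits (0.0468 and 0.047), and Hedgehog genes passed in 5 FPKM fits (adjusted p from 0.0339 to 0.0421).

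Of 103 genes named as changed, 66 kept the call in each of the 6 fits without 1 library and 8 in none. Of the 102 other than Nf2, 23 lost the call with the replicate block and 23 with limma-trend on FPKM without a filter. No filter on low counts ended 8 calls, DESeq2 size factors 3 and DESeq2 0. The other FPKM fits, in which fewer of these genes were tested, ended 3 to 11. Each library held at least 50906043 counts, and depth limits genes with a count of 0 over a group, for which only a bound can be given.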

Other observations

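The tests of the on and off genes, of macrophages, of fewer mitochondria, of the random placement and loss of a copy of each chromosome region and of Elob were chosen only after the result was seen; those of the other splits, of length, GC content, scaling and random placement of the fullest window were not. Among genes with a mean FPKM of at least 1, the largest rises in Nf2-knockout libraries included Msln, the gene of the cell-surface glycoprotein mesothelin. It rose from 20.5 ± 3.24 to 158 ± 60.7 CPM (mean ± SD, n = 3, log2 fold change 2.95). The serpin gene Serpinb9b rose from 25.6 ± 9.88 to 161 ± 30 CPM (2.65) and the microtubule regulator gene Stmn2 from 10.1 ± 3.52 to 82.9 ± 13.6 CPM (3.04). Nkain4 rose from 2.85 ± 0.605 to 45.3 ± 13.9 CPM (3.99). Sostdc1, a secreted antagonist of BMP and Wnt signalling, rose from 0.383 ± 0.0853 to 4.05 ± 0.869 CPM (3.40). The largest falls included the lipocalin gene Apod from 23.8 ± 4.34 to 2.89 ± 1.54 CPM (−3.04), the prostaglandin D synthase gene Ptgds from 15.2 ± 3.8 to 1.89 ± 0.535 CPM and the secreted ligand gene Wnt2b from 10.9 ± 1.8 to 1.46 ± 0.412 CPM (−2.89). Each of these genes kept its call with 1 library left out. Whether the changes lay in chondrocytes or in a different mix of cells was not tested.

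Single genes taken from several of the strongest terms changed in both directions. Igf1, the gene of insulin-like growth factor 1, fell from 407 ± 44.3 to 129 ± 30.2 CPM (log2 fold change −1.65), the adenylyl cyclase gene Adcy5 from 33.9 ± 0.77 to 11.5 ± 2.84 CPM (−1.56), the pro-apoptotic gene Bcl2l11 from 26.2 ± 0.914 to 10.6 ± 1.34 CPM (−1.31) and Sod2, mitochondrial superoxide dismutase, from 129 ± 2.84 to 75.1 ± 5.78 CPM (−0.78). Rprm, which encodes a cell cycle regulator induced by p53, rose from 4.78 ± 0.873 to 14.9 ± 1.95 CPM (1.64), and the kinase gene Cdk6 from 28.8 ± 0.565 to 47.9 ± 4.06 CPM (0.73).

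The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. For changed genes 1 split reached the real 1693 (the real one), and the highest other had 3. For genes changed at least 2-fold 1 split reached 747, and the highest other had 3. For terms 1 split reached 90, and the highest other had 48. For gene lists 4 splits gave at least the real 10, and the highest other had 12. In all, 43 genes had no count in any library of one group and at least 10 in each library of the other, 20 without counts in Nf2-knockout and 23 in control; 1 split reached 43, and the highest other had 15.

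Interferon genes and macrophage markers fell together. The RNA of macrophages themselves may account for part of the interferon fall. As its whole cause, with an equal interferon share in all macrophages, it is opposed by the single libraries. Interferon CPM was 1542, 1626 and 1451 in the controls, at 164.4, 440.5 and 217.1 CPM of markers. It was 953.2, 977.5 and 745.8 in the Nf2-knockout libraries, at 115.5, 88.8 and 50.2 CPM of markers. The interferon list lost from 1.84 to 12.04 times the CPM that the markers lost over the 9 pairs of a control and a knockout library, 647.5 against 189.2 CPM in the mean, but the share of interferon genes in the RNA of these macrophages was not measured, so the ratio decides nothing. A signal from macrophages to the chondrocytes may also contribute: control replicate 2 had 2.31 times the marker CPM of the other 2 controls but 1.09 times their interferon CPM, which too few libraries keep open. A lower interferon state of Nf2-knockout chondrocytes, the group the design names, also stays open and was not tested.

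Nuclear genes of oxidative phosphorylation fell together with the share of mitochondrial counts. The list's transcripts are short, with a median of 1661 against 2894 bases for other tested genes, yet genes of matched length had a median log2 fold change of 0.0229 (−0.187 to 0.207 over 1000 drawn lists), and genes of matched GC content 0.0075 (−0.173 to 0.197), against −0.41 for the list. Scaling argues little for it either, since the list median closest to 0 over 3 scalings was −0.26. Fewer mitochondria per cell could lower the genes of the mitochondrial chromosome but need not lower the nuclear list. On that chromosome 33 of 36 tested genes were lower, with a median of −0.35. Only mt-Nd2 passed the test, and its call was held in 0 of 6 fits without 1 library. Several of the 36 had few counts, such as mt-Tf at 0.293 CPM in Nf2-knockout and 0.326 CPM in control libraries. Genes of the same chromosome may also vary together, so 33 of 36 is a count and not a test. For the mitochondrial genes, fewer mitochondria and lower transcription cannot be told apart from RNA alone. An effect of the Nf2 deletion on either, or on the nuclear genes, stays open as untested.

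Falls of genes lay close together on 3 chromosomes. The fullest windows of 11 neighbouring tested genes held 9 falls on chromosome 16 and 8 on chromosome 9, numbers that 0 of 1000 shuffles of the falls over the genome reached, which argues against random placement of these. The fullest window on chromosome 11 held 7, the most in any shuffle and reached in 6 of 1000. Random placement would thus rarely give it, but is not excluded there. The fullest window of rises held 5. The regions lie on chromosome 11 (88339382 to 90638084, 11 of 17 tested genes fell, median −0.74), chromosome 16 (42875881 to 44746363, 10 of 15, median −1.09) and chromosome 9 (5298508 to 7581415, 8 of 11, median −1.06, with Mmp3, Mmp10, Mmp12, Mmp13 and Mmp27, the last called in 1 of 6 fits without 1 library). Loss of 1 of 2 copies as the whole cause on chromosome 9 is opposed by Mmp12 (−4.47), Mmp10 (−2.17), Mmp3 (−2.58) and Mmp13 (−2.53). Each lies below a log2 fold change of −1 by more than 3 SE, while 4 of the 11 tested genes lie above −1 by more than 2 SE. Among the latter, Pdgfd was higher at 0.64 (SE 0.255), but it was not called, also in 0 of 6 fits without 1 library. Reads of Elobl (99.2 CPM lost) did not turn up under its paralog Elob, which changed by −10.3 CPM. On chromosome 11, loss of 1 of 2 copies as the whole cause is opposed by 3 genes, Elobl (−6.43), 2210409E12Rik (0 counts in Nf2-knockout) and Hlf (−2.16). They lie below a log2 fold change of −1 by more than 3 SE, a distance that for 2210409E12Rik depends on the prior count. Loss of a copy may account for falls among the other 14 genes there (14 of 14 lower, highest −0.26, 6 of them above −1 by more than 2 SE) and on chromosome 16 (15 of 15 lower, highest −0.34, 3 above −1 by more than 2 SE, lowest Zdhhc23 at −1.88, SE 0.333, called in 2 of 6 fits without 1 library), but not without loss in only part of the cells or compensation for the genes above −1. There the RNA cannot tell it from shared regulation or from a stretch of another mouse strain, neither of which was tested.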
